A study of Arabidopsis thaliana with 12 samples.

How the data were processed

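Seedlings of Arabidopsis thaliana Col-0 and ixr1-1 were grown in shaken liquid medium under 16 h of light and 8 h of dark and treated at an age of 6 days for 1 h with 600 nM isoxaben or with DMSO, per the labels' protocols. Seedlings from a single flask were divided between an isoxaben and a DMSO flask, per the labels. RNA was extracted with a plant total RNA kit and 500 ng went into a stranded mRNA library kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, FastQC 11.1, STAR 2.4.1 and featureCounts 1.4.6, with no role or order. The genome build, the annotation, the strand setting of the counting and whether reads were single or paired are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be told apart.

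The deposited values are raw counts per gene, 1 file per library, in the format of featureCounts per the file headers, with 33602 genes, 0 features without a gene name and 0 columns of other series. Nothing in the files shows a normalization. Gene positions are those of the files. For 27998 genes found both there and in the TAIR10.1 reference, 21.5% had the same start and end. In addition 97.7% of 120956 gaps between the files' exons began with GT and ended with AG on TAIR10.1, so the files' exon positions fit that sequence while gene ends follow another annotation. Gene names were taken from the reference for 32835 of the 33602 genes and 20301 of the 20379 tested.

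The 12 libraries form 4 groups of 3, with groups and replicate numbers from the labels. Totals ran from 8521491 to 20658035 counts, and the 10 most counted genes took 4.03 to 4.66% of a library. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in 1 model over the 12 libraries with a term per group, in R 4.3.3. The 5 comparisons were isoxaben against DMSO in Col-0 and in ixr1-1, ixr1-1 against Col-0 in DMSO and in isoxaben, and the interaction. P-values were adjusted by Benjamini-Hochberg within each comparison over the 20379 tested genes, with a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. CPM are scaled by TMM factors, and the median SE over genes was 0.107 and 0.109 for the treatment in Col-0 and ixr1-1, 0.153 for the interaction and 0.108 for both genotype comparisons. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with a 95% counting interval. Both cover counting error only.

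Before the data were examined, 25 gene lists with 421 loci were fixed from general knowledge of the field; 399 were tested and 22 had too few counts. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 25 lists, and also with an estimated correlation and with fry. Genes were named by a rule fixed before the data were examined. It takes CESA3 and up to 12 rising and 8 falling genes with the largest log2 fold change past the threshold. These need an average log2 CPM of at least 1 and no overlap between the libraries of the groups (overlap was not asked for the interaction). It also takes up to 4 passing members of each list by adjusted p, or the 1 with the smallest unadjusted p where none passed. Not every gene it takes is printed. Lists of 14 seed storage and oil body genes, 12 late embryogenesis and dormancy genes and 4 embryo regulators were added after the data were seen. EM1 and EM6 were left out of the late embryogenesis list because their counts had been seen before.

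Near-identical copies were sought with blastn 2.17.0 (at least 95% identity): 9 of 492 genes named or listed have one, 48 overlap exons on the opposite strand and 2 on the same strand. Replicates were compared by a chi-square of their counts per degree of freedom, which was at least 2.77 for each pair.

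Alternatives fixed before the data were examined were DESeq2 size factors, library size alone, no filter, a filter of 1 CPM in 6 libraries, and DESeq2 1.42.0. Further ones were limma-voom without and with sample quality weights, only the groups compared, a replicate block by flask or by number, each library left out, and a fold of at least 2 as well. For the lists they were the estimated correlation, fry, DESeq2 size factors, no filter, a prior count of 0.5, the block and each library left out. Chosen after the data were seen were the summed seed storage level as a covariate, its log2, thinning of all libraries to 8521491 counts, and leaving out both ixr1-1 libraries numbered 1.

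The fit was tested on simulated counts of 20232 genes with known changes, placed in genes with a mean of at least 1 CPM. Each gene had the same dispersion in all groups, so the shares below do not compare the spread of the genotypes. Of genes changed 2-fold, 77.6% were called for isoxaben in Col-0, 91.0% in ixr1-1, 72.4% for the interaction, and 91.0% and 92.0% for the genotypes in DMSO and isoxaben. For 1.5-fold these were 59.7, 73.1, 46.3, 68.7 and 77.6%. Unchanged genes made up 9.90, 4.89, 5.50, 8.51 and 5.06% of the calls in the same order, so the share of false calls was above the nominal 0.05 in 4 of the 5. A jasmonate list shifted 2-fold was recovered by camera, by camera with an estimated correlation and by fry. The last also called 1 list that was not shifted. Genes were drawn independently and all 28 members moved the same way, so this cannot judge the tests where genes of a list correlate. Comparisons that share control libraries were set against 20 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9.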

Results

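Transcript levels were measured by mRNA sequencing in Arabidopsis thaliana seedlings of the wild type Col-0 and of ixr1-1, an isoxaben-resistant line with a point mutation in CESA3. CESA3 is a catalytic subunit of the complex that makes cellulose in primary walls, and isoxaben is a herbicide that inhibits cellulose synthesis. Seedlings aged 6 days were kept for 1 h in liquid medium with 600 nM isoxaben or with the solvent DMSO, which gave 4 groups of 3 libraries. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Total counts per library in the order of the replicate numbers were 15140660, 14733295 and 19470898 for Col-0 DMSO and 10490825, 17963734 and 14448316 for Col-0 isoxaben. For ixr1-1 DMSO they were 8521491, 20658035 and 10060546, and for ixr1-1 isoxaben 10838409, 13648295 and 14558491. Of 33602 genes in the files, 20379 had enough counts to be tested. No pair of replicates agreed within sampling noise: the chi-square per degree of freedom between replicates lay between 2.77 and 6.80. The first principal component held 49.1% of the variance and separated the genotypes, whereas the next held 8.62% and 7.82%. Levels are given as TMM-scaled CPM, mean ± SD with n = 3 per group, and changes as log2 fold changes ± SE with the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test, unless another tool is named.

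CESA3 itself (AT5G05170, chromosome 5, 1530174 to 1535414) was at 579 ± 21 CPM in Col-0 DMSO, 566 ± 38 in Col-0 isoxaben, 588 ± 69 in ixr1-1 DMSO and 603 ± 96 in ixr1-1 isoxaben. The genotypes differed by 0.02 ± 0.10 in DMSO (adjusted p = 0.91) and by 0.09 ± 0.10 in isoxaben (adjusted p = 0.63), less than the spread between libraries. The level of a transcript with a point mutation does not check the genotype labels. Coordinates are those of the deposited files, whose genome build is not given in the sources used here.

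The comparison of isoxaben with DMSO in Col-0 asks which transcripts respond in the wild type within 1 h. Of the fixed lists, 9 of 22 rapid stress transcription factors and 6 of 22 receptors and signalling genes of pattern-triggered immunity rose, and neither list was called with an estimated correlation (adjusted p = 0.0964 and 0.254). ERF13 (AT2G44840, chromosome 2, 18495341 to 18496272), an ethylene response factor, rose 9.59-fold from 0.594 ± 0.21 to 5.89 ± 0.79 CPM (log2 3.26 ± 0.25, adjusted p = 5.7e-07). CNGC19 (AT3G17690, chromosome 3, 6045002 to 6048488), a cyclic nucleotide gated cation channel, rose 5.45-fold from 2.73 ± 0.95 to 14.6 ± 1.6 CPM (adjusted p = 0.0036). PROPEP3 (AT5G64905, chromosome 5, 25939574 to 25940059), the precursor of a danger peptide perceived by the PEPR receptors, rose 4.95-fold from 0.985 ± 0.27 to 4.80 ± 0.26 CPM (adjusted p = 0.00082). AT4G25250 (chromosome 4, 12934562 to 12935373), annotated as a pectin methylesterase inhibitor, fell from 17.04 ± 3.3 to 6.20 ± 1.1 CPM (log2 -1.47 ± 0.20, adjusted p = 0.0024).

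In total 125 genes rose and 34 fell, which is 0.780% of the genes tested; 71 of the risen and 6 of the fallen genes changed by at least 2-fold. An unadjusted p under 0.05 was found for 1387 genes, where chance alone gives about 1019. DESeq2 called 193 genes, 149 of them shared, and limma-voom 146, with 136 shared. The count fell to 77 without library 3 of Col-0 DMSO, to 79 without library 2 of Col-0 isoxaben and to 93 with all libraries thinned to the smallest total, and it rose to 243 when only the 6 Col-0 libraries entered the fit. With a replicate block by flask it was 367 and with a block by number 233. The labels do not say that a replicate number marks a flask.

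The other genes with the largest rises, at an average log2 CPM of at least 1, were AT3G44870, annotated as a methyltransferase (log2 4.15 ± 0.60), the EF-hand protein AT3G29000 (3.39 ± 0.34), AT5G28610 (3.11 ± 0.24), the cytochrome P450 CYP706A2 (2.64 ± 0.29) and the phloem protein PP2-B14 (2.45 ± 0.30). Next came the expansin-like EXLA3 (2.37 ± 0.23), AT1G13480 (2.28 ± 0.29), the glutathione transferase GSTU12 (2.25 ± 0.32) and AT5G41750, a resistance protein of the TIR-NBS-LRR class (2.25 ± 0.21). Their adjusted p lay between 5.7e-07 and 0.0076. Reads of CYP706A2 cannot be told apart from those of its near-identical neighbour AT4G22690, and AT3G44870 overlaps exons of AT3G44880 on the same strand. The largest falls after AT4G25250 at that level were those of CYP718 (-1.45), the pectin lyase-like AT1G05650 (-1.20), ROH1 (-1.12), CYP51G2 (-1.07), the receptor-like kinase AT5G24100 (-1.01), GRI (-0.98) and COBL9 (-0.91), a COBRA-like protein of root hairs. The last of these went from 12.3 ± 0.53 to 6.63 ± 0.64 CPM (adjusted p = 0.0051). In a design of 3 against 3, 10% of unchanged genes show no overlap between the groups, which was a condition for naming these genes. The calls of CYP51G2, GRI and ROH1 each ended when any 1 of 4 Col-0 libraries was left out, with an adjusted p of up to 0.18, 0.21 and 0.078, and without library 2 of Col-0 isoxaben those of COBL9 (0.066) and CYP718 (0.052) ended too. GRI overlaps exons on the opposite strand, and the strand setting of the counting is not given in the sources used here.

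**Figure D1:**
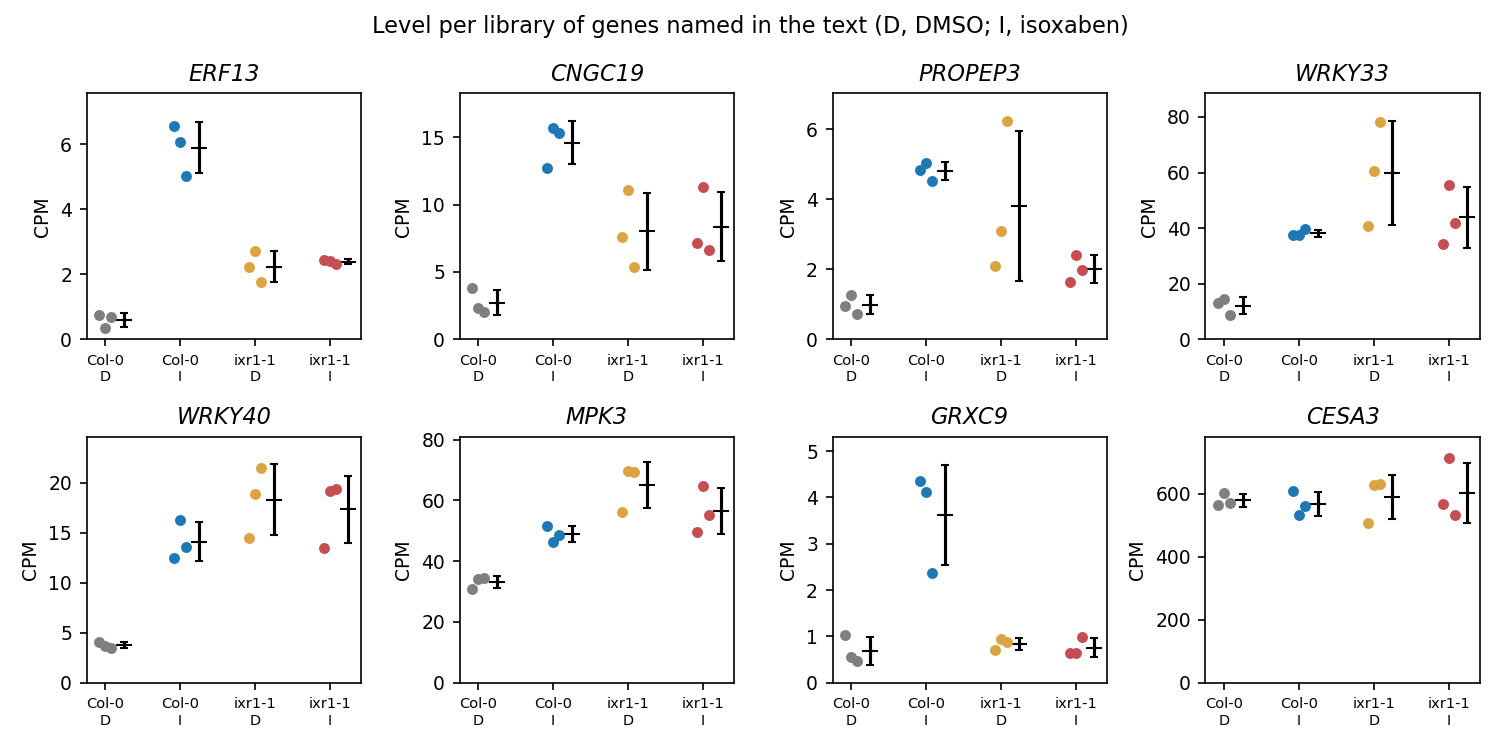
CPM of 8 genes in each of the 12 libraries (points) with the group mean ± SD, n = 3, on linear axes from 0. ERF13 rose from 0.594 to 5.89 CPM with isoxaben in Col-0 and was at 2.23 and 2.39 CPM in ixr1-1 with DMSO and isoxaben, while CESA3 lay between 566 and 603 CPM in all group means.

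Of the 25 gene lists fixed before the data were examined, 8 were called by limma's camera with a preset correlation, and none remained when the correlation between genes was estimated (smallest adjusted p = 0.0964). Limma's fry, which asks only whether a list moves on balance, called 4. These were the rapid stress transcription factors (adjusted p = 0.0075), salicylate, ethylene, and touch and calcium (0.0371 each). The rapid stress transcription factors had 9 of 22 members that rose and 0 that fell (14 rose when adjusted over the list alone; camera adjusted p = 7.69e-22, and adjusted p = 0.0964 with an estimated correlation). ERF13, WRKY40 (3.80-fold, 3.76 ± 0.32 to 14.1 ± 2.0 CPM, adjusted p = 1.6e-05), the zinc finger gene CZF1 (log2 1.00) and NAC062 (0.51) led this list. Receptors and signalling of pattern-triggered immunity, the response to microbial or damage-derived molecules, had 6 of 22 members that rose (6 when adjusted over the list alone; camera adjusted p = 9.19e-10, adjusted p = 0.254 with an estimated correlation). These were PROPEP3, PROPEP1 (1.33), PROPEP2 (2.17) and PROPEP4 (0.82), the receptor gene PEPR2 (1.28) and the kinase gene MPK3 (0.56, adjusted p = 0.0061). Of the 12 marker genes of pattern-triggered immunity 1 rose, WRKY33 (3.20-fold, 12.1 ± 3.0 to 38.2 ± 1.3 CPM, adjusted p = 0.041), and 4 rose when adjusted over the list alone (camera adjusted p = 2.90e-06, adjusted p = 0.343 with an estimated correlation). PROPEP2 and PROPEP4 lie outside the rule for named genes and were added after their values were seen. The WRKY33 call ended when any 1 of the 6 Col-0 libraries was left out (adjusted p of up to 0.19), and without library 2 of ixr1-1 DMSO (0.082) or library 3 of ixr1-1 isoxaben (0.080). WRKY33, WRKY40 and PEPR2 overlap exons of genes on the opposite strand.

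Of 18 genes of salicylate synthesis and response 5 rose and 0 fell, among them GRXC9 (log2 2.41), NPR3 (1.04), PAD4 (0.67) and WRKY38 (4.31 ± 0.81), whose level in Col-0 isoxaben was 3.71 ± 3.3 CPM. In this list 6 rose when adjusted over the list alone (camera adjusted p = 1.56e-07, adjusted p = 0.169 with an estimated correlation). Of 20 genes of ethylene synthesis and response 3 rose, ERF6 (1.72, adjusted p = 4.7e-06), ERF11 (1.38) and ERF5 (1.23), and 6 when adjusted over the list alone (camera adjusted p = 3.42e-09, adjusted p = 0.169 with an estimated correlation). The calls of ERF5 (adjusted p of up to 0.16), ERF11 (0.16) and WRKY38 (0.22) ended without 6, 4 and 9 of the 12 libraries taken out in turn. In the touch and calcium response list 1 of 16 members rose, the calmodulin-like CML39 (6.98-fold, adjusted p = 2.8e-06), and 4 when adjusted over the list alone (camera adjusted p = 5.09e-07, adjusted p = 0.169 with an estimated correlation). No member of the cell cycle list (17 genes, camera upward, adjusted p = 0.00864) or of the phenylpropanoid and lignin list (18 genes, camera downward, adjusted p = 0.0178) passed the gene test, and with an estimated correlation the adjusted p was 0.681 and 0.805. The cell cycle call for isoxaben against DMSO in Col-0 ended without library 2 of Col-0 DMSO (adjusted p = 0.234) or library 3 of Col-0 isoxaben (0.117). The phenylpropanoid call ended without library 1 or 2 of Col-0 DMSO (0.0646 and 0.0701) or library 3 of Col-0 isoxaben (0.0505).

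In Col-0, 0 of 15 members of the list of primary wall cellulose synthesis passed, and 0 of 12 of the list of secondary wall formation, which also holds xylan, laccase, protease and transcription factor genes (camera adjusted p = 0.330 and 0.173). By unadjusted edgeR p the nearest to the threshold were CC2 (log2 -0.11, adjusted p = 0.95) and FRA8 (-0.27, adjusted p = 0.28). Of the 22 wall remodelling enzymes 1 rose, XTH20 (0.53, adjusted p = 0.049; 3 when adjusted over the list alone), and of the 16 root markers 1 fell, COBL9. The XTH20 call ended when any 1 of 9 libraries was left out (adjusted p of up to 0.26). The median of the root markers was 0.03, their mean -0.06, and camera gave the direction down (adjusted p = 0.436). No member passed among 21 genes of wall integrity sensing, 28 of jasmonate synthesis and signalling, and 11 of indole glucosinolate and camalexin synthesis. None passed among 24 of detoxification and oxidative stress, 16 of abscisic acid and osmotic stress, 14 of auxin response, 10 of cytokinin response and 9 of brassinosteroid synthesis and response. The same held for 11 genes of the circadian clock, 12 of hypoxia response, 11 of heat shock and the unfolded protein response, 16 shoot photosynthesis markers and 6 reference genes. Adjusted over the list alone, 2 jasmonate genes rose and 1 fell, 1 detoxification and 1 auxin gene rose, and 3 brassinosteroid genes fell. The jasmonate median was -0.04 and its mean 0.02, with camera pointing down (adjusted p = 0.706). Median and mean also differed in sign from camera's direction, or from each other, for the heat shock list (median 0.00091, mean -0.01, camera down) and the photosynthesis list (0.0078 and 0.0037, camera down), neither of them called.

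The same treatment in ixr1-1 asks whether the response needs the CESA3 form that isoxaben can inhibit. No gene passed in ixr1-1. ERF13 was at 2.23 ± 0.48 CPM with DMSO and 2.39 ± 0.068 with isoxaben, CNGC19 at 8.01 ± 2.9 and 8.37 ± 2.6, and WRKY40 at 18.3 ± 3.6 and 17.35 ± 3.3. The 125 genes that rose in Col-0 had a median log2 fold change of -0.05 in ixr1-1 (interquartile range -0.19 to 0.07) against 1.10 in Col-0. The 34 that fell had a median of 0.07 against -0.68. limma's fry gave the 2 sets an unadjusted p of 0.818 and 0.330 for a move on balance in ixr1-1, and 0.314 and 0.0398 for changes in either direction.

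**Figure D2:**
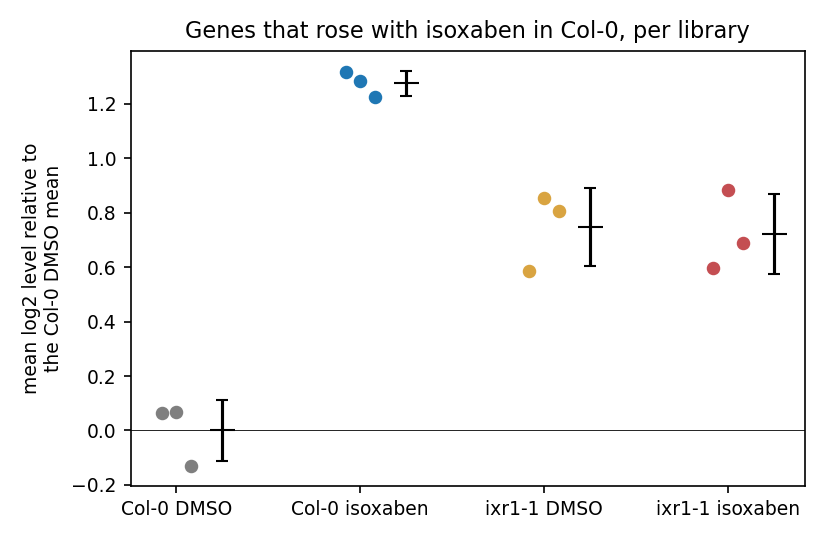
Mean log2 level of the 125 genes that rose with isoxaben in Col-0, per library, relative to the mean of Col-0 DMSO, with mean ± SD per group, n = 3. Col-0 isoxaben libraries lay at 1.27 ± 0.05, ixr1-1 DMSO at 0.75 ± 0.14 and ixr1-1 isoxaben at 0.72 ± 0.15; the genes were chosen for their difference between the Col-0 groups.

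The count of 0 came from edgeR, and DESeq2 and limma-voom also called 0, each without a replicate block. In edgeR a block by flask called 13 genes and a block by number 1, though the labels do not say that a replicate number marks a flask. Without a block 742 genes had an unadjusted edgeR p under 0.05, fewer than the 1019 that chance gives. The smallest adjusted p was 0.694. The median SE over genes was 0.109, beside 0.107 in Col-0. These values do not compare the spread of the genotypes, since the model estimates dispersion over all groups together. With each genotype fitted apart, the common biological coefficient of variation was 0.0846 in ixr1-1 and 0.0678 in Col-0. In counts simulated with the shared dispersion, edgeR called 91.0% of genes changed 2-fold and 73.1% of those changed 1.5-fold in this comparison. The changed genes had a mean of at least 1 CPM, so these shares do not cover lower levels or the spread of ixr1-1 fitted apart. Across all genes the log2 fold changes of the 2 genotypes had a Pearson r of -0.009, a value over genes, which are not independent replicates. With the level of seed storage transcripts as a covariate, an alternative chosen after seeing the data, 1 gene was called.

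Camera with the preset correlation called 5 lists in ixr1-1 though 0 of their members passed. Cytokinin response (adjusted p = 0.0209) and cell cycle (0.0247) pointed up, and markers (0.0135) and receptors (0.0217) of pattern-triggered immunity and auxin response (0.0247) pointed down. With an estimated correlation their adjusted p was 0.775, and that of fry 0.838. The number of lists fell to 1 without library 2 of ixr1-1 DMSO and without library 1 or 3 of ixr1-1 isoxaben, to 2 without library 3 of ixr1-1 DMSO, and rose to 10 without library 2 of ixr1-1 isoxaben. Members nearest to the threshold in these lists were ARR6 (log2 0.37), KNOLLE (0.22), CYP81F2 (-0.69), PROPEP3 (-0.89) and PIN3 (-0.20). Among the indole glucosinolate genes 1 was higher, MYB122 (1.04), and 1 lower when adjusted over the list alone.

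**Figure D3:**
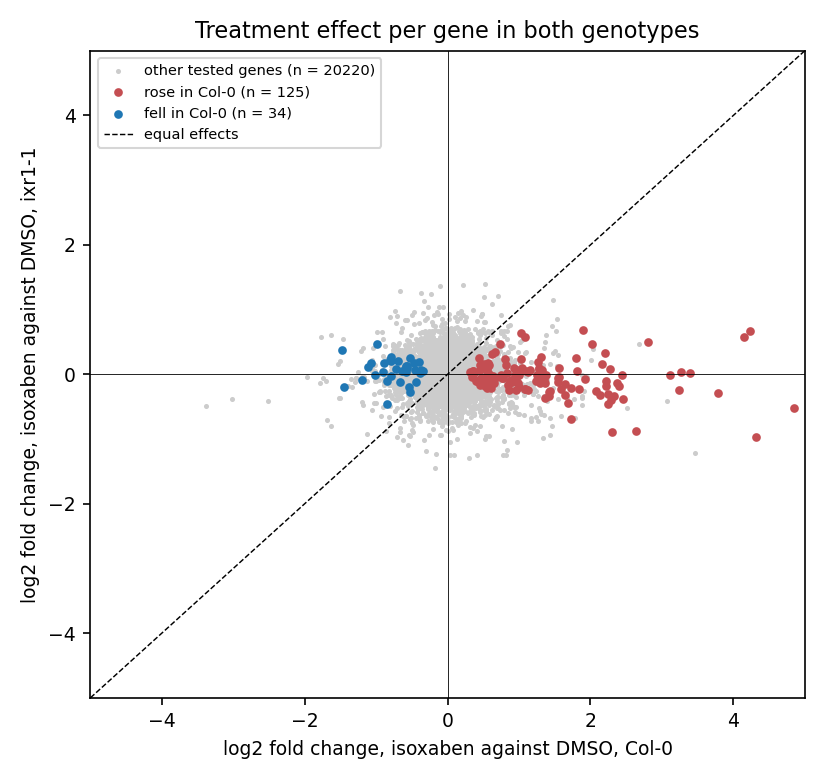
Log2 fold change with isoxaben in Col-0 (horizontal) against that in ixr1-1 (vertical) for 20379 genes: 125 that rose in Col-0 (red), 34 that fell (blue) and all others (grey), with the line of equal change dashed. The risen genes spread along the horizontal axis, with medians of 1.10 in Col-0 and -0.05 in ixr1-1.

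The difference of the treatment effects, ixr1-1 minus Col-0, was tested as an interaction. The effect of isoxaben was lower in ixr1-1 for ERF13 (-3.22 ± 0.35, adjusted p = 0.00015), PROPEP3 (-3.20 ± 0.44, 0.0019), WRKY40 (-2.003 ± 0.23, 0.00052) and MPK3 (-0.76 ± 0.14, 0.016). It was higher for genes that had fallen in Col-0, such as AT4G25250 (1.85 ± 0.28, adjusted p = 0.011) and AT1G05650 (1.11 ± 0.16, 0.002). Of the 125 genes that rose in Col-0, 51 passed this test, all of them lower in ixr1-1, and the median difference was -1.12; of the 34 that fell, 12 passed, all higher, with a median of 0.72. The MPK3 call ended without library 1 of Col-0 DMSO or of Col-0 isoxaben (adjusted p = 0.055 each), library 2 or 3 of ixr1-1 DMSO (0.085 and 0.051) or library 3 of ixr1-1 isoxaben (0.064), and that of AT4G25250 without library 2 of ixr1-1 DMSO (0.072). The gene sets were chosen by the Col-0 effect, which is part of this difference, so their medians lie away from 0 by choice as well.

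In all, 52 genes were lower and 12 higher, 38 and 6 of them by at least 2-fold. An unadjusted p under 0.05 was found for 971 genes, fewer than the 1019 that chance gives. DESeq2 called 104 genes, 62 of them shared, and limma-voom 55. The count was 22 without library 2 of ixr1-1 DMSO, 28 without library 3 of Col-0 DMSO, 29, 37 and 113 without library 3, 1 or 2 of ixr1-1 isoxaben, and 36 without library 2 of Col-0 isoxaben. With a replicate block by flask it was 180 and with a block by number 99, a pairing that the labels do not give. Camera called 6 lists, all downward. The rapid stress transcription factors had 6 of 22 members lower (12 when adjusted over the list alone; adjusted p = 9.24e-20). The others were receptors and signalling (3 of 22, 10; 3.93e-12) and markers (0 of 12, 5; 1.53e-08) of pattern-triggered immunity, touch and calcium (1 of 16, 4; 1.25e-08), salicylate (2 of 18, 5; 2.62e-08) and ethylene (1 of 20, 5; 1.13e-07). With an estimated correlation none was called (smallest adjusted p = 0.127), and fry called the rapid stress transcription factors alone (adjusted p = 0.0411). The number of lists was 10 without library 1 of Col-0 isoxaben.

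The comparison of ixr1-1 with Col-0 in DMSO asks how the genotypes differ without the inhibitor. Seed storage transcripts were the largest difference. CRU3 (AT4G28520, chromosome 4, 14087556 to 14089796), a cruciferin storage globulin, had 0 counts in the Col-0 DMSO libraries and 6329 in ixr1-1, at least 2653-fold higher against a floor of 3 counts over the group. CRU1 (AT5G44120, chromosome 5, 17756264 to 17758288) was at 0.0878 ± 0.11 CPM in Col-0 and 170 ± 80 in ixr1-1 (log2 10.86 ± 1.39, adjusted p = 0.0011). Of the fixed lists, 16 of 22 receptors and signalling genes of pattern-triggered immunity, 14 of 20 ethylene genes and 9 of 16 touch and calcium genes were higher in ixr1-1, while 10 of 24 detoxification genes were lower and 2 higher. None of the lists was called with an estimated correlation (smallest adjusted p = 0.189). CYP81F2 (8.10-fold), WRKY33 (5.03-fold), WRKY40 (4.92-fold) and CML12 (2.98-fold) were among the genes higher in ixr1-1.

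The summed level of 14 seed storage and oil body genes, a list added after the data were seen, was 2.41 ± 1.06 CPM in Col-0 DMSO and 1.83 ± 0.58 in Col-0 isoxaben, but 532 ± 270 in ixr1-1 DMSO and 419 ± 287 in ixr1-1 isoxaben. The 3 ixr1-1 DMSO libraries held 226, 739 and 630 CPM and the 3 ixr1-1 isoxaben libraries 116, 454 and 686 CPM, so that each ixr1-1 library lay above each Col-0 library. In DMSO 13 of the 14 genes were higher in ixr1-1, and SESA5 did not pass (adjusted p = 0.165). The list's median log2 fold change was 6.89, and 6.94 with genes at the floor set to their bound. SESA3 had 3 counts in Col-0 DMSO (ratio 1084, 95% counting interval 371 to 5260), OLEO1 had 2 (ratio 538, 149 to 4451) and OLEO2 had 2 (ratio 165, 45.2 to 1367). AT2G28490, another cupin, had 0 and was at least 187-fold higher. CRU2 (9.02), SESA1 (7.84), SESA4 (6.80), SESA2 (5.98), PDF1.2 (5.52) and PAP85 (4.56) completed the 12 largest at an average log2 CPM of at least 1. The calls of CRU3 (adjusted p = 0.034), AT2G28490 (0.042) and PDF1.2 (0.045) ended when any 1 of 7, 7 and 9 libraries was left out, with an adjusted p of up to 0.10, 0.14 and 0.13. Those of CRU2 and SESA3 ended without library 1 (0.056 and 0.085) or 3 (0.062 and 0.055) of Col-0 DMSO. Ratios, floors and intervals cover counting error only, and OLEO1 overlaps exons on the opposite strand. Late embryogenesis genes were far lower in level. Of 12 such genes 9 were tested and 4 were higher. Their highest level in ixr1-1 DMSO was 2.93 CPM, against 193 CPM for the most counted storage gene, both from summed counts. It was that of LEA4-5, which was not higher in ixr1-1 (log2 -0.45, adjusted p = 0.21). EM1 and EM6 were left out of the 12 because their counts had been seen before. In DMSO EM1 had 0 counts in Col-0 and 11 in ixr1-1, and EM6 had 6 and 5.

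**Figure D4:**
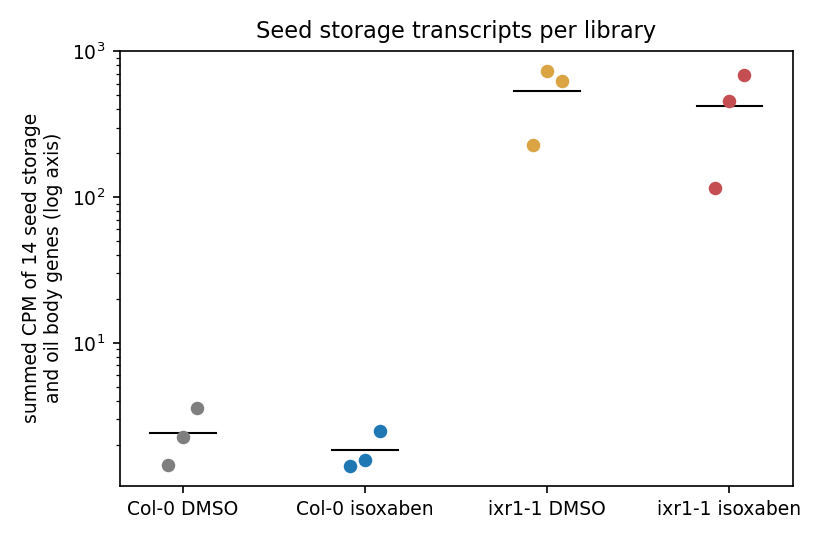
Summed CPM of 14 seed storage and oil body genes per library on a log axis, with a line at each group mean. The 6 Col-0 libraries lay between 1.43 and 3.54 CPM and the 6 ixr1-1 libraries between 116 and 739 CPM.

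The genotypes differed in 3509 genes (17.2% of those tested) in DMSO, 1996 higher and 1513 lower in ixr1-1; 532 and 88 of them by at least 2-fold, with 6162 genes at an unadjusted p under 0.05. Scaling by library size alone gave, for ixr1-1 against Col-0 in DMSO, 2716 higher and 926 lower. The count was 2281 without library 2 of ixr1-1 DMSO, 339 with the summed seed storage level as a covariate (r with genotype 0.82) and 0 with its log2 (r = 0.98), both chosen after seeing the data. The genes furthest below Col-0, at an average log2 CPM of at least 1, were QQS (-3.03 ± 0.25, adjusted p = 2.6e-07), the alternative oxidase AOX1B (-2.38 ± 0.45), SAG29 (-2.36 ± 0.32) and GSTU25 (-2.11 ± 0.38; 221 ± 25 and 52.3 ± 25 CPM). They were followed by the gibberellin oxidase GA2OX7 (-1.995 ± 0.16), AT1G03990 (-1.98 ± 0.34), AT4G23050 (-1.87 ± 0.09, adjusted p = 1.9e-10) and the anion channel SLAH1 (-1.78 ± 0.34).

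Camera called 15 lists in DMSO, 9 up and 6 down, and none with an estimated correlation (smallest adjusted p = 0.189); fry, which asks whether a list moves on balance and not whether it exceeds other genes, also called 15, with the circadian clock (down, adjusted p = 0.0455) in place of secondary wall formation (0.154). The same libraries also differed in the seed storage transcripts, at 532 ± 270 CPM in ixr1-1 DMSO and 2.41 ± 1.06 in Col-0 DMSO. None of these list differences can be told apart from that difference. Receptors and signalling of pattern-triggered immunity had 16 of 22 members higher and 0 lower (17 adjusted over the list alone; camera adjusted p = 2.84e-10, adjusted p = 0.198 with an estimated correlation), among them MPK3 (0.98) and the receptor genes EFR (1.02) and FLS2 (AT5G46330, 1.52). Of the 12 markers 7 were higher (9; 3.12e-07, adjusted p = 0.216 with an estimated correlation), among them CYP81F2, WRKY53 (2.64) and WRKY33. Ethylene synthesis and response had 14 of 20 higher and 0 lower (17 higher and 1 lower adjusted over the list alone; 2.84e-10, adjusted p = 0.189 with an estimated correlation), with the receptors ETR2 (1.30) and ERS1 (0.55) and the response factor ERF1A (1.58). Of the rapid stress transcription factors 14 of 22 were higher (17; 1.16e-10, adjusted p = 0.189 with an estimated correlation), led by WRKY15 (2.82-fold) and WRKY40 (2.30, adjusted p = 4.9e-07). The touch and calcium list had 9 of 16 higher (11; 4.75e-06, adjusted p = 0.189 with an estimated correlation), with CML12 at 185 ± 16 CPM in Col-0 and 550 ± 77 in ixr1-1. EFR and FLS2 lie outside the rule for named genes and were added after their values were seen.

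Smaller upward calls follow with the adjusted p at the preset and then at the estimated correlation. They came from jasmonate synthesis and signalling (10 of 28 higher, 1 lower; 10 and 2 adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.475 with an estimated correlation) and wall integrity sensing (8 of 21 higher, 1 lower; 9 and 1; 0.00951, then 0.370). They also came from salicylate (6 of 18 higher, 1 lower; 6 and 1; 0.0177, then 0.461) and wall remodelling (6 of 22 higher, 3 lower; 10 and 3; 0.0254, then 0.461). JAZ10 (1.18), the wall-associated kinase WAK2 (1.37), the calcium channel component MCA2 (1.34), CBP60G (1.85) and the xyloglucan enzymes XTH19 (4.05-fold) and XTH23 (2.12-fold) were higher. For ixr1-1 against Col-0 in DMSO, leaving out library 2 of ixr1-1 DMSO ended the jasmonate call (adjusted p = 0.086) and leaving out library 1 of Col-0 DMSO that of wall remodelling (0.0522).

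Downward calls came from indole glucosinolate and camalexin synthesis (6 of 11 lower, 1 higher; 7 and 1 adjusted over the list alone; camera adjusted p = 3.70e-04, adjusted p = 0.189 with an estimated correlation), with CYP79B2 (-0.57) and CYP83B1 (-0.44). Detoxification and oxidative stress was lower too (10 of 24 lower, 2 higher; 12 and 3; 0.00119, adjusted p = 0.253 with an estimated correlation). Its members UGT74E2 (-1.12) and CYP81D11 (-1.60) were lower but AOX1A (0.95) was higher. Shoot photosynthesis markers (4 of 16 lower; 5; 0.00103, adjusted p = 0.475 with an estimated correlation) included RBCS3B (-0.42), while RCA (adjusted p = 0.053) and RBCS1A (0.10) no longer passed when scaled by library size alone, nor without 4 and 8 of the libraries taken out in turn (adjusted p of up to 0.10 and 0.21). Brassinosteroid genes (3 of 9 lower, 2 higher; 6 and 2; 0.0322, adjusted p = 0.461 with an estimated correlation) had lower synthesis genes, CPD (-0.68) and BR6OX2 (-0.76), and higher transcription factors, BES1 (0.52) and BZR1 (0.43). The 6 reference genes had 1 lower, GAPC1 (-0.42; 2 adjusted over the list alone; 0.0254, adjusted p = 0.189 with an estimated correlation). The secondary wall list had 1 of 12, FRA8 (-0.29, adjusted p = 0.031 and 0.083 with library size alone, up to 0.11 with any 1 of 4 libraries left out; 0 adjusted over the list alone; 0.0254, adjusted p = 0.475 with an estimated correlation). For ixr1-1 against Col-0 in DMSO, neither was called without library 1 of ixr1-1 DMSO (adjusted p = 0.072 and 0.216), and brassinosteroid was not called without library 2 of Col-0 DMSO (0.0682) or library 3 of ixr1-1 DMSO (0.0621). CYP81D11, BZR1, WRKY33, WRKY40, WRKY53 and WAK2 overlap exons on the opposite strand.

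Camera did not call the remaining lists in DMSO. Phenylpropanoid genes had 3 higher and 3 lower of 18, abscisic acid 2 and 2 of 16, and hypoxia 2 and 2 of 12. Heat shock had 1 and 2 of 11, cytokinin 2 and 1 of 10, auxin 2 and 0 of 14, root markers 0 and 2 of 16, and the clock 0 and 1 of 11. None of the 17 cell cycle genes and none of the 15 primary wall cellulose genes passed in edgeR; the nearest of the latter was CC1 (0.16, adjusted p = 0.13), and 0 passed when adjusted over the list alone.

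**Figure D5:**
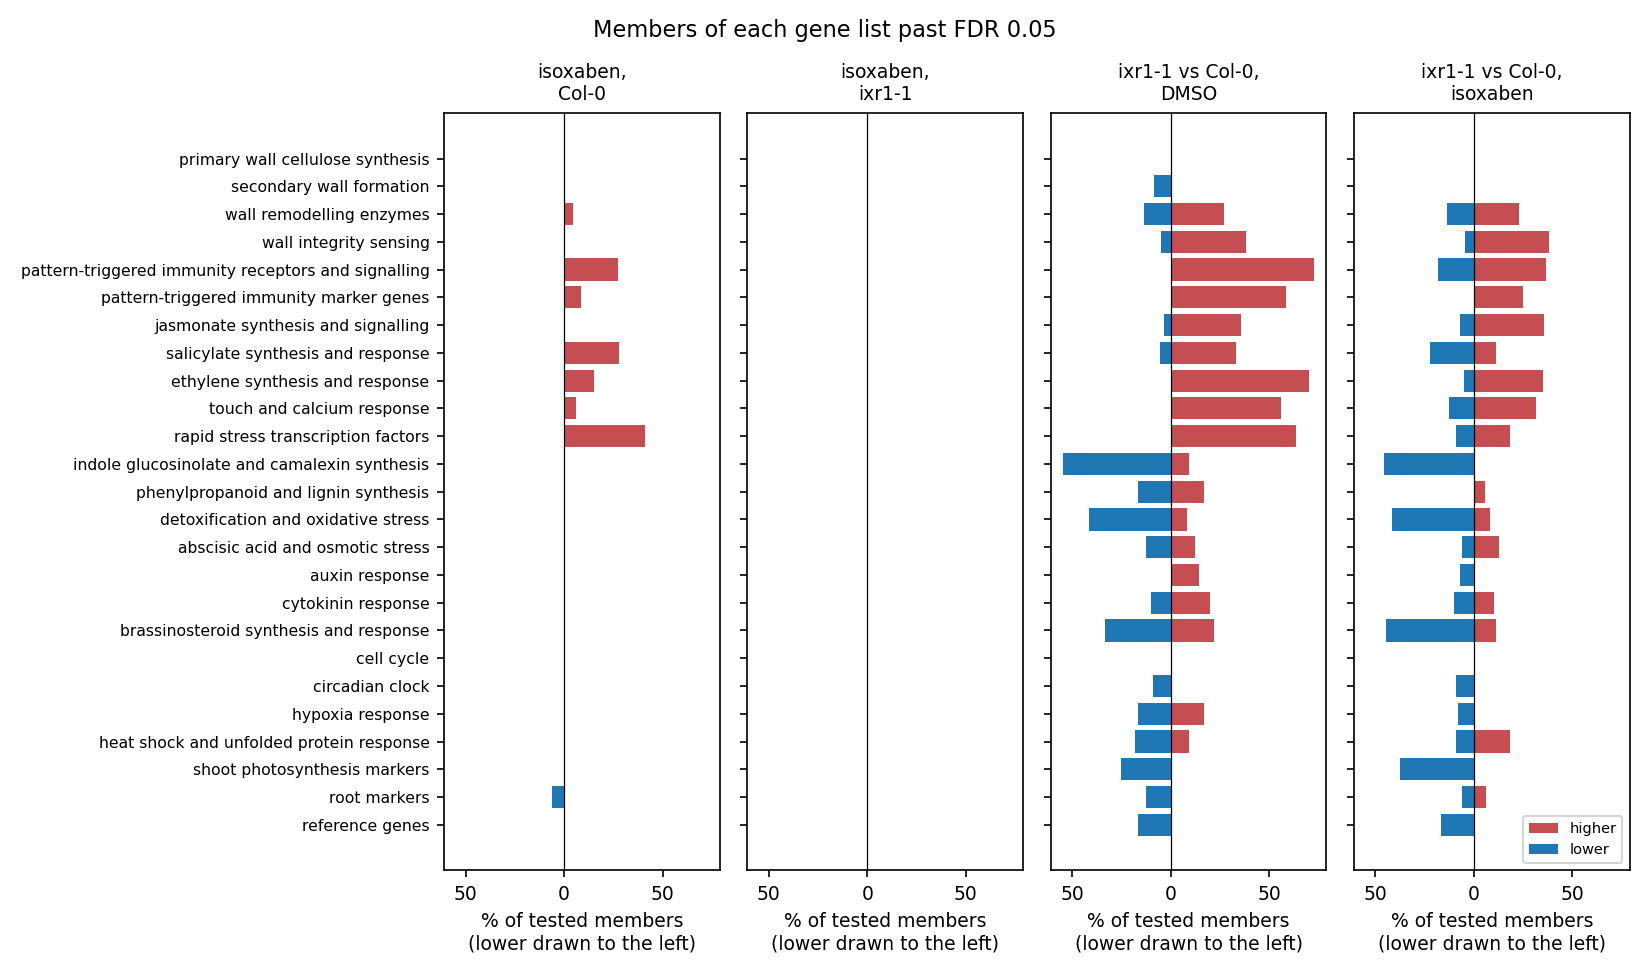
Percent of the tested members of each of the 25 lists past an adjusted p of 0.05, higher to the right and lower to the left, for isoxaben in Col-0 and in ixr1-1 and for ixr1-1 against Col-0 in DMSO and in isoxaben. Receptors and signalling of pattern-triggered immunity had 6 of 22 members higher with isoxaben in Col-0, 0 in ixr1-1, and 16 and 8 higher in ixr1-1 than in Col-0 in DMSO and in isoxaben.

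Of the 125 genes that rose with isoxaben in Col-0, 76 were higher in ixr1-1 in DMSO and 3 lower, with a median log2 fold change of 0.78; of the 34 fallen genes 6 were lower and 0 higher, with a median of -0.16. Both comparisons use the same Col-0 DMSO libraries, and with unchanged simulated ixr1-1 groups the median of the most risen genes was 0.18 on average and 0.22 at most in 20 simulations. The simulations drew each gene independently and so leave out noise that genes share. Independent lists of these sizes would share 12.2 genes upward and 2.52 downward, beside the 76 and 6 observed. The covariance of the log2 fold changes across genes was 0.041, against 0.015 simulated, and their r was 0.31 against 0.47. With the Col-0 treatment effects kept in the simulation, the covariance was 0.016, the r 0.28 (0.25 to 0.31) and the median 0.072 (at most 0.12); these simulations called 558 to 695 genes for isoxaben in Col-0, against 159 observed, so their treatment effects are too large. The 3 control libraries cannot be split into parts of at least 2, and part of the excess may come from them. With each Col-0 DMSO library left out of the choice of genes and used alone as the control, the median was 0.69, 0.67 and 1.00.

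In isoxaben the comparison of the genotypes asks what remains of their difference under the inhibitor. The seed transcripts were again the largest difference among called genes: SESA3 was at least 704-fold, CRU2 at least 530-fold and OLEO1 at least 229-fold higher in ixr1-1, and CRU1, with 1 count in Col-0, had a ratio of 6241 (95% counting interval 1120 to 246557). CRU3, with 0 counts in Col-0 and 4684 in ixr1-1, was at least 1716-fold higher but was not called (adjusted p = 0.0514). The calls of SESA3, CRU2 and OLEO1 ended when any 1 of 4, 4 and 2 libraries was left out (adjusted p of up to 0.075, 0.075 and 0.056 in edgeR). Of the 125 genes that had risen with isoxaben in Col-0, 53 were lower and 6 higher in ixr1-1 and the others did not pass; among the lower ones were CML39 (-2.56 ± 0.25, adjusted p = 3.8e-06), GRXC9 (-2.21 ± 0.31, 0.00016), ERF13 (-1.29 ± 0.20, 0.00033), PROPEP3 (-1.24 ± 0.29, 0.0095) and PEPR2 (-0.98 ± 0.16, 0.00065). ETR2 (1.31) and ERS1 (0.49), which encode ethylene receptors, WAK2 (1.01) and XTH23 (0.85) were higher in ixr1-1, and XTH20 was lower (-0.79).

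Of 2602 genes (12.8%) 1410 were higher and 1192 lower, 332 and 103 of them by at least 2-fold, and 5482 had an unadjusted p under 0.05. Scaling by library size alone gave, for ixr1-1 against Col-0 in isoxaben, 2280 higher and 721 lower. The count was 1549 and 1712 without library 2 or 3 of ixr1-1 isoxaben, 1664 and 1570 without library 2 or 3 of Col-0 isoxaben, 309 with the seed storage covariate and 0 with its log2. The remaining named genes with the largest differences were SESA1 (ratio 362, 123 to 1756), OLEO2, SESA4 (adjusted p = 0.053 without library 2 of Col-0 isoxaben), SESA2, PAP85, the receptor-like protein RLP21 (3.63 ± 0.41), AT4G38560 (3.14 ± 0.27) and OLEO4 (3.06 ± 0.34). Furthest below Col-0, at an average log2 CPM of at least 1, were AT3G44870 (-4.18 ± 0.63), QQS (-3.63 ± 0.27), AT1G47405 (-2.55 ± 0.32), AOX1B (-2.39), GSTU25 (-2.04), SLAH1 (-1.92), IPS1 (-1.87), a non-coding RNA induced by phosphate starvation, and SAG29 (-1.82).

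Camera called 6 lists in isoxaben, and none with an estimated correlation (smallest adjusted p = 0.289); fry called 6, with the reference genes (down, adjusted p = 0.00514) in place of jasmonate (0.108). The seed storage sum was 419 ± 287 CPM in ixr1-1 isoxaben and 1.83 ± 0.58 in Col-0 isoxaben, and none of these calls can be told apart from that difference. Ethylene (7 of 20 higher, 1 lower; 9 and 1 adjusted over the list alone; camera adjusted p = 0.00334, adjusted p = 0.723 with an estimated correlation) pointed up. So did jasmonate (10 of 28 higher, 2 lower; 11 and 2; 0.0199, then 0.728) and wall integrity sensing (8 of 21 higher, 1 lower; 8 and 1; 0.0369, then 0.723). Photosynthesis markers (6 of 16 lower; 11; 4.32e-05, adjusted p = 0.723 with an estimated correlation), indole glucosinolate genes (5 of 11 lower; 7 lower and 1 higher; 9.39e-04, then 0.289) and detoxification (10 of 24 lower, 2 higher; 13 and 3; 9.49e-04, then 0.516) pointed down. For ixr1-1 against Col-0 in isoxaben, without library 2 of ixr1-1 isoxaben the jasmonate and wall integrity calls ended (adjusted p = 0.19 and 0.155), the latter also without library 3 of Col-0 isoxaben (0.133). Receptors and signalling of pattern-triggered immunity went both ways (8 higher, 4 lower of 22). So did salicylate (2 higher, 4 lower of 18, with GRXC9, NPR3, WRKY38 and PR1 lower), the rapid stress transcription factors (4 and 2 of 22) and touch and calcium (5 and 2 of 16), none of them called by camera. The other lists camera did not call in isoxaben were wall remodelling (5 higher, 3 lower), markers of pattern-triggered immunity (3 and 0), abscisic acid (2 and 1) and heat shock (2 and 1). The same held for brassinosteroid (1 and 4), cytokinin, root markers (1 and 1 each), phenylpropanoid (1 and 0), auxin, the clock, hypoxia and reference genes (0 and 1 each), and secondary wall, cell cycle and primary wall (0 and 0).

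Of the 125 genes that rose with isoxaben in Col-0, 53 were lower and 6 higher in ixr1-1 in isoxaben, with a median of -0.43, and of the 34 that fell 25 were higher and 1 lower, with a median of 0.52. Independent lists would share 7.31 and 2.35 genes in these opposite directions. With unchanged simulated groups the shared Col-0 isoxaben libraries gave a median of -0.17, and a covariance of -0.016 beside the -0.026 observed. With the Col-0 treatment effects kept and ixr1-1 unchanged, the median was -1.17 (-1.28 to -1.10) and the covariance -0.076, but these are the simulations with 558 to 695 calls in Col-0 and do not give a fair benchmark.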

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

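The tests against shared control libraries and against a larger spread in ixr1-1 were chosen after the result was seen, as were the seed storage covariate on both scales and thinning, the use of leave-one-out ranges as the spread, and the seed gene lists.

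The response to isoxaben differed between the genotypes by the interaction test in 64 genes. Effects in ixr1-1 minus Col-0, as log2, were -3.52 for CYP706A2, -3.38 for AT3G29000, -3.22 for ERF13, -3.20 for PROPEP3, and -3.12 for AT5G28610. They were -2.83 for PP2-B14, -2.71 for GSTU12, and -2.69 for AT1G13480. For rapid and defence genes they were -2.59 for GRXC9, -2.31 for CML39, -2.003 for WRKY40, -1.93 for ERF6, -1.70 for ZAT10, -1.19 for PEPR2, -1.02 for CZF1, -0.95 for NPR3 and -0.76 for MPK3. Taken out in turn, 9 of the 12 libraries each ended the calls of CML39, NPR3 and PEPR2, and 8 that of GRXC9 (adjusted p of up to 0.35, 0.15, 0.22 and 0.27). Effects were 0.60 for AT4G30170, 0.65 for AT1G08590, 0.66 for AGP14, 0.69 for AGP4, 0.79 for HB-3, 0.91 for AT4G13620, 1.02 for AT4G31320, 1.06 for CER4, 1.07 for ARP1, 1.11 for AT1G05650, 1.44 for GRI and 1.85 for AT4G25250. The medians of the 6 lists called were -0.35 for receptors and signalling and -0.76 for markers of pattern-triggered immunity, -0.49 for salicylate, -0.46 for ethylene, -0.30 for touch and calcium and -0.58 for rapid stress transcription factors. With an estimated correlation none was called (smallest adjusted p = 0.127). Of 60 splits drawn from 200 possible ones, 2 gave as many genes as the real split, itself included, with 64 genes in the real and 90 in the highest other. Most of these splits break up the Col-0 treatment groups and so do not test the difference between the genotypes. The 7 drawn that keep them gave 23 to 54 genes, too few splits to exclude chance.

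Isoxaben called 0 genes in ixr1-1 (edgeR without a replicate block, with 742 at an unadjusted p under 0.05, and 0 also by DESeq2 and limma-voom). A block by flask called 13, but the labels do not say that a replicate number marks a flask. Depth as the cause is argued against by the 93 genes called in Col-0 when all libraries were thinned to the smallest total, 87 of them among the 159. A larger spread that hides a response of the same size is argued against by the median of the 125 genes, -0.054 in ixr1-1 (-0.12 to 0.003 leaving out each library), below the bound set at 0.27. Levels already raised in ixr1-1 may account for part of it and stay open: 12 responsive genes that were not higher in ixr1-1 under DMSO had a median of 0.288 with isoxaben (0.15 to 0.33), on both sides of the bound of 0.294. These genes were chosen by their ixr1-1 DMSO level, the baseline of that change, which pushes the value upward, so it decides nothing. The resistance of ixr1-1 to isoxaben, the biological difference the design names, stays open too and was not tested apart from this.

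Of the 125 genes that rose with isoxaben in Col-0, 76 were higher and 3 lower in ixr1-1 without it, with a median of 0.78 over all 125. Shared Col-0 DMSO libraries as the whole cause are argued against by simulations that reached at most 0.221. These drew genes independently and so leave out noise that genes share. With each Col-0 DMSO library left out of the choice and used alone as the control, the median was 0.69, 0.67 and 1.00. Those medians also argue against that cause. After thinning the median was 0.747 (0.69 to 0.81), above the bound of 0.39. Random thinning leaves expected fold changes as they were, so it could not decide on depth. Seed RNA stays open: the median was 0.688 with the seed storage covariate (0.44 to 0.70 leaving out each library) but 0.449 with its log2 (0.22 to 0.84), on both sides of the bound, and these covariates follow genotype with r = 0.82 and 0.98. The mean of these genes was 0.586, 0.853 and 0.806 in the ixr1-1 DMSO libraries, at 226, 739 and 630 CPM of storage RNA, and 0.596, 0.882 and 0.688 in the isoxaben libraries, at 116, 454 and 686 CPM, too few to decide. Altered cellulose synthesis in ixr1-1 and another culture history may each contribute and were not tested.

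Seed storage transcripts were high in each ixr1-1 library. Dry or ungerminated seeds in the cultures may be the source: the 9 tested late embryogenesis genes had a median of 2.05, which met the condition set beforehand. Over all 12 genes, with those at the floor set to their bound, it was 1.78. But their highest level, that of LEA4-5, was 2.93 CPM against 193 CPM for storage genes, and LEA4-5 was not higher in ixr1-1. EM1 and EM6, left out of this list, had 11 and 5 counts in ixr1-1 DMSO and 0 and 6 in Col-0 DMSO. A further condition, a late embryogenesis level of at least 0.1 of that of storage genes, was added after these values were seen and was not met, so seeds remain open. An embryonic programme in the seedlings cannot be told apart from this either, since the most counted embryo regulator reached 0.459 CPM and none of the 4 had enough counts to be tested. FUS3 had 1 count in Col-0 and 11 in ixr1-1 in DMSO (ratio 13.8, 2.01 to 595), and 0 and 16 in isoxaben (at least 5.86-fold higher). The others went both ways. In Col-0 and ixr1-1 in DMSO, ABI3 had 6 and 18 counts, LEC2 12 and 7, and LEC1 1 and 1. In isoxaben ABI3 had 12 and 17, LEC2 16 and 9, and LEC1 1 and 0. Which genotype effects follow from such material is not resolved.

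The splits of 3 against 3 are too few for a share under 0.05. Each other split also mixes 2 libraries of a group with 1 of the other, so a real difference widens the spread within its sides. Few or no calls there do not by themselves argue against chance. The real split called 159 genes for isoxaben in Col-0 and the highest other 0, with 1 of 10 as large; for ixr1-1 against Col-0 these were 3509 and 0 in DMSO and 2602 and 0 in isoxaben, with 1 of 10 each. For isoxaben in ixr1-1 all 10 of 10 gave at least the 0 genes of the real one, and the highest other gave 130. That split had ixr1-1 DMSO library 1 and isoxaben libraries 1 and 3 on a side, which points to a structure of the ixr1-1 libraries other than the treatment.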

How the results depend on the processing

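The seed storage covariate on a linear and a log2 scale, thinning and the fit without both ixr1-1 libraries numbered 1 were chosen after seeing the data. Counts of genes for isoxaben in Col-0, in ixr1-1, the interaction and the genotypes in DMSO and isoxaben were 159, 0, 64, 3509 and 2602. Over the libraries left out they ranged from 77 to 193, 0 to 0, 22 to 113, 2281 to 3798 and 1549 to 2756, and lists called from 6 to 10, 1 to 10, 6 to 10, 13 to 17 and 5 to 9. DESeq2 called 104 genes for the interaction. A fit of only the 2 groups gave 243 in Col-0. At least 2-fold as well left 77, 620 and 435 for Col-0 and the genotypes. The covariate gave 1 in ixr1-1, 339 and 309 for the genotypes, its log2 gave 167, 0, 56, 0 and 0 in the order above, and thinning 93 in Col-0; without both libraries numbered 1 counts were 178, 0, 56, 3208 and 2383. The cause was not tested, but the covariate follows genotype (r = 0.82, and 0.98 for its log2) and thinning takes depth away. Camera with an estimated correlation called 0 lists in each comparison, and fry 4 in Col-0, 0 in ixr1-1 and 1 for the interaction.

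A replicate block by flask gave 367 genes in Col-0, 13 in ixr1-1 (1 higher, 12 lower) and 180 for the interaction, and cannot be fitted for the genotypes. A block by number gave 1 in ixr1-1 and 99 for the interaction. Deviations of same-numbered samples correlated with r = 0.03, 0.14 and 0.21 in Col-0 and 0.23, 0.31 and 0.03 in ixr1-1. Between different numbers r ran from -0.31 to 0.11, and 10 of 12 samples correlated best with their own number. These values go with a pairing by number. It is not settled, since r was as low as 0.03 and the labels do not tie a number to a flask.

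Of 931, 723, 2419 and 2138 fits of the named called genes under alternatives, for Col-0, the interaction and the genotypes, 858, 560, 2146 and 1900 kept direction and call and 0, 0, 24 and 26 turned direction, all with the log2 covariate; the rest lost the call. CESA3, never called, turned sign with single libraries left out. Its log2 fold change then ranged from -0.084 to 0.013 for isoxaben in Col-0, -0.102 to 0.118 in ixr1-1, -0.071 to 0.150 for the interaction, -0.025 to 0.125 for the genotypes in DMSO and -0.046 to 0.174 in isoxaben. It was also -0.015 in ixr1-1 with quality weights, -0.019 there without both libraries numbered 1, and -0.125 and -0.022 for the genotypes with the covariate. In ixr1-1 the range was -0.016 to 0.207 for CESA5 and -0.0015 to 0.248 for PHT1;1, neither called. The cause was not tested. Thinning took the interaction from 64 to 48 genes, 44 of them shared, and Col-0 from 159 to 93, 87 of them shared.

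With the log2 seed storage level as covariate (r with genotype 0.98), the log2 fold change of some named genes turned its sign. For ixr1-1 against Col-0 in DMSO these were SESA1 (-0.30), SESA4 (-0.9993), SESA2 (-0.34), PAP85 (-0.61), AOX1B (2.13), GSTU25 (0.81), SLAH1 (0.076), CC1 (-0.12) and FRA8 (0.25). Further ones were WAKL10 (-1.95), JAZ10 (-0.17), MYB34 (0.00602), CAD4 (0.055), CCR2 (-0.24), AOX1A (-0.22), ABF3 (0.074), HAB1 (0.13) and CKX4 (-0.058). Further ones were CPD (0.37), LBD41 (-0.45), PCO1 (-0.58), HSP70-4 (0.91), BIP3 (-0.077), HSP90.1 (0.38), RBCS1A (0.025) and CESA3 (-0.43). For ixr1-1 against Col-0 in isoxaben these were SESA1 (-0.015), SESA4 (-1.69), SESA2 (-0.46), PAP85 (-0.18), AOX1B (1.91), GSTU25 (0.81), CC1 (-0.069), LAC17 (0.015) and WAKL10 (-1.665). Further ones were WRKY22 (-0.30), WRKY53 (-0.94), PR1 (0.98), WRKY38 (2.18), ERS2 (-0.056), EBF1 (-0.0999), WRKY15 (-0.067), AOX1A (-0.35) and CYP81D11 (0.19). Further ones were CYP81D8 (-0.38), ABF3 (0.21), GH3.1 (0.0032), CKX4 (-0.017), CPD (0.17), RVE1 (0.066), HSP70-4 (0.88), HSP18.2 (-0.14) and PSBO1 (0.022). Further ones were GAPC1 (0.0045) and CESA3 (-0.36). CC1, CESA3 and, in isoxaben, LAC17 were not called before either. The fit can hardly separate such a covariate from genotype, and it called 0 genes in either comparison. SESA1, SESA2, SESA4 and PAP85 are themselves part of the summed level, so a turn there says nothing. For the other genes the cause was not tested.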

Other observations

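In lists that camera did not call, single members differed between ixr1-1 and Col-0 in DMSO (edgeR, n = 3 per group). PDC1, a pyruvate decarboxylase of fermentation, was lower in ixr1-1 (40.8 ± 9.8 and 13.5 ± 2.6 CPM in Col-0 and ixr1-1, log2 -1.62 ± 0.24, adjusted p = 0.0016), whereas LBD41 (1.53) and PCO1 (0.70), other members of the hypoxia list, were higher. Among heat shock genes the cytosolic chaperones HSP70-4 (-0.76) and HSP90.1 (-0.68) were lower and BIP3 (1.56), a chaperone of the endoplasmic reticulum, was higher. The nitrate transporter gene NRT2.1 (-1.10), the aquaporin gene TIP2;3 (-0.50) and the clock gene RVE1 (-0.92) were lower. The response regulator genes of the cytokinin list went both ways, with ARR9 lower (-0.53) and ARR16 higher (2.11 ± 0.37 and 4.41 ± 0.51 CPM).

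These differences cannot be told apart from that in the seed storage transcripts, at 532 ± 270 CPM in ixr1-1 DMSO and 2.41 ± 1.06 in Col-0 DMSO. In isoxaben PDC1 (-1.46), HSP70-4 (-0.76), NRT2.1 (-1.35) and RVE1 (-0.58) were lower in ixr1-1 too, while TIP2;3 (-0.16, adjusted p = 0.31), HSP90.1 (-0.38, 0.21), BIP3 (1.26, 0.069), LBD41 (0.91, 0.16), PCO1 (0.31, 0.38) and ARR16 (0.61, 0.051) did not pass. In DMSO the calls of NRT2.1 (adjusted p of up to 0.14), PCO1 (0.094), LBD41 (0.13), BIP3 (0.10) and HSP90.1 (0.089) each ended without 2 to 4 of the libraries taken out in turn. In isoxaben those of HSP70-4 (0.073) and NRT2.1 (0.052) ended without library 2 of ixr1-1 isoxaben, the former also without library 3 (0.055).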
